A study of Caenorhabditis elegans with 4 samples.

How the data were processed

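Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed on adult *Caenorhabditis elegans* of the mutant strain *fem-2(b245)* with an affinity-purified rabbit antibody against T09A5.8. The gene name table of assembly WBcel235 gives T09A5.8 the symbol *cec-3*. Per the labels' protocols, frozen adults were ground, fixed in 1% formaldehyde for 10 min and sonicated, and the libraries were read as single ends on Illumina instruments. The culture temperature was 20 °C. The series holds 4 samples in 2 groups, T09A5.8 ChIP and input DNA, with 2 replicates in each. No label says whether the replicates came from separate cultures, so the spread between them may be technical.

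The values used were 3 deposited peak lists. Reads were aligned with BWA to the build ce10, per the submitters' processing notes, and the lists give positions on WormBase WS220, per the file headers. Per the source column of the files, each ChIP replicate has a list made with MACS and the whole series has a further list made with MACS v2. The version behind the replicate lists, the control used, the thresholds and the way the replicates enter the whole-series list are not given in the sources used here. Each peak carries a score that the authors' caller assigned and the authors deposited with no statement of its scale. The lowest score was 50.1 in replicate 1, 50.07 in replicate 2 and 1.3 in the whole-series list. Scores of the replicate lists pile up at 3100, which 447 peaks of replicate 1 and 559 of replicate 2 carry. Scores of the whole-series list are on another scale and were not compared with those of the replicates. The input samples have no peak list of their own and enter no comparison. The lists give no read counts, so the read depth of each sample is unknown and no statement about background in the input could be made. No peak of one replicate had the same start and end as a peak of the other, so the lists were treated as 2 samples.

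Peaks of a list do not overlap one another. Peaks of different lists were called overlapping when they shared at least 1 bp. The overlap of the replicates was set against 1000 circular shifts of one list along each chromosome, which keep the number, width and spacing of its peaks, and the p-value is the one-sided share of shifts with as many overlaps. The lengths of chromosomes I to V and X were taken as the largest peak end in any list, 100.272 Mb in total. Each chromosome was divided into 3 parts of equal length, here called the left arm, the centre and the right arm, and a peak was placed by its midpoint. Densities are peaks per Mb, given as the mean ± SD of the 2 ChIP replicates. The share of peaks on X was tested with a two-sided exact binomial test against the share of X in the length, and arms were tested against centres with a two-sided exact sign-flip permutation test over the 6 chromosomes. Binomial tests and the 95% Wilson intervals of shares cover counting error only, since neighbouring peaks are not independent. The overlap function was tested on 3797 simulated peaks, made narrower than the real ones. With 80.1% of peaks kept in a second list, 80.1% were found. A set arm-to-centre log2 ratio of 2 came out as 2.05 and a set X-to-autosome ratio of 0.25 as 0.226. These ratios were counted separately in the simulation, so the functions that gave the densities reported below were not themselves tested. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.

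The tests, the alternatives and the rule for named peaks were set before the data were examined, except where the text says otherwise. The alternatives were other overlap rules, the better-scoring peaks of each list, lists of equal length, the whole-series list, bases covered in place of peaks counted, other arm limits and leaving out each replicate. The rule names the 10 highest-scoring whole-series peaks that overlap a peak of both replicates, by position. A test of 25 gene lists, of gene features and of repeats had also been set, and applied only with an annotation of the files' build. The gene coordinates at hand are of WBcel235, a later build, so they were not set against WS220 positions, and genes under the peaks are not analysed here.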

Results

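The binding sites of T09A5.8 were mapped by ChIP-seq in *fem-2(b245)* adults that contain a germline. T09A5.8 is CEC-3, a chromodomain protein that binds histone H3 methylated at lysine 9, a mark of heterochromatin. *fem-2* acts in sex determination and is needed for sperm formation. The authors' lists hold 3666 peaks for ChIP replicate 1, 3867 for ChIP replicate 2 and 14075 for the whole series. The peaks covered 12.4% of the 100.272 Mb between the chromosome ends in replicate 1, 12.6% in replicate 2 and 12.8% in the whole-series list, although the median peak width was 2067.5 bp, 2043 bp and 395 bp in that order. The read depth is unknown. The comparisons asked whether the replicates found the same sites and how the sites lie along the chromosomes, between X and the autosomes and between chromosome arms and centres.

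The replicates marked largely the same sites. A peak of replicate 2 overlapped 3264 of the 3666 peaks of replicate 1, or 89.03% (95% Wilson interval 88.0 to 90.0%). A peak of replicate 1 overlapped 3300 of the 3867 peaks of replicate 2, or 85.3% (84.2 to 86.4%). Shifting one list along the chromosomes gave a mean of 24.8% and a highest value of 44.0% for replicate 1, and a mean of 23.8% and a highest value of 42.4% for replicate 2. The one-sided p was 0.001 for both, the smallest that 1000 shifts can give. Shifts of 50 to 500 kb, an alternative added after the data were seen, keep most peaks within their own arm. They gave means of 41.3% and 39.8%. At the level of bases, the lists shared 10.9 Mb, which is 88.0% of the bases of replicate 1 and 86.2% of those of replicate 2. Across 3547 overlapping pairs of peaks, the scores of the replicates had a Spearman's rho of 0.75, and peaks are not independent replicates. It was 0.891 over the 2615 pairs in which each peak met a single partner.

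The sites that only one replicate found were weaker and narrower in the median than the shared ones. In replicate 1 the unshared peaks had a median score of 86.3 and a median width of 1139 bp, against 469 and 2288 bp for the shared ones. In replicate 2 the medians were 104.1 and 1201 bp against 598 and 2286.5 bp. With peaks ranked by score into 4 groups of equal number, the shared part of replicate 1 was 65.8% in the lowest group, 92.6% in the next, and 98.8% and 98.9% above. In replicate 2 it was 58.8%, 87.4%, 97.0% and 98.1%. On X, 31.6% of the peaks of replicate 2 were unshared, 56 of 177, against 13.8% on the autosomes (two-sided Fisher's exact test, p = 5.3e-09, counting error only). In replicate 1 the values were 11.8% and 10.9% (the same exact test, p = 0.68). This comparison of X with the autosomes was chosen after the data were seen.

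The whole-series list held more and narrower peaks than the replicate lists. Of its 14075 peaks, 7578 or 53.8% (95% Wilson interval 53.0 to 54.7%) overlapped a peak of both replicates, 2699 overlapped a peak of one and 3798 of neither. Those in both had a median score of 10.2 and a median width of 692 bp. Those in neither had a median score of 4.55 and a median width of 230 bp. Conversely, 99.7% of the peaks of replicate 1 and 99.5% of those of replicate 2 overlapped a whole-series peak.

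The X chromosome was the sparsest, with 0.207 times the peak density of the autosomes. X had 9.06 ± 1.32 peaks per Mb and the autosomes had 43.7 ± 1.44 (SD, n = 2), a ratio of 0.207 ± 0.0233. X held 144 peaks in replicate 1 and 177 in replicate 2, which is 3.93% and 4.58% of all peaks for 17.67% of the length (two-sided exact binomial tests, p = 6.6e-144 and 1.4e-134, counting error only). An exact permutation of the label of X among the 6 chromosomes cannot go below p = 0.167. Among autosomes, I was the densest with 63.8 ± 1.60 peaks per Mb, followed by III with 53.5 ± 0.667. Chromosomes II, IV and V had 34.7 ± 1.48, 35.8 ± 1.66 and 35.84 ± 1.622 (SD, n = 2 for each). The peaks covered 22.2% of I and 18.4% of III, but 2.68% of X, as means of the replicates. In the whole-series list they covered 21.6% of I, 17.9% of III and 4.02% of X. Within the centres alone, where autosomes are themselves sparse, the X-to-autosome ratio was 0.253 in the replicates.

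Chromosome arms held most of the sites on every chromosome. The arms, which make up 66.7% of the length, held 89.9 ± 0.296% of the peaks (SD, n = 2). Averaged over the 6 chromosomes, peak density in arms was 4.29-fold that in centres, a log2 ratio of 2.101 ± 0.263 (SD over 6 chromosomes). The ratio was positive on all 6 chromosomes in both replicates (two-sided exact sign-flip test on the mean of the replicates, p = 0.031, the smallest that 6 chromosomes allow). It was largest on I, with a log2 ratio of 2.61 ± 0.0215, and the lowest mean was that of X, with 1.85 ± 0.180 (SD, n = 2 for each). The value of X in replicate 2, 1.97, lay above that of III, 1.95, and that of IV, 1.93, in the same replicate, so X was not separated from them beyond the replicates' spread. In the whole-series list the log2 ratio was 2.16 on X, 2.11 on III and 2.05 on IV. The log2 ratios of II, III, IV and V were 2.03 ± 0.0494, 2.03 ± 0.108, 1.98 ± 0.0717 and 2.12 ± 0.0300.

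The arms of a chromosome were not equally dense. On V the right arm had 71.9 ± 2.33 peaks per Mb and the left arm 24.5 ± 1.82. On IV the order was the other way, with 69.4 ± 2.06 on the left and 26.0 ± 1.82 on the right. X had 16.3 ± 1.44 on the left and 7.62 ± 2.39 on the right. III had 84.6 ± 0.462 on the left and 58.4 ± 1.08 on the right, and II had 54.4 ± 1.67 and 38.3 ± 1.94. Both arms of I were dense, with 81.8 ± 2.53 on the left and 95.1 ± 1.69 on the right. Centres ranged from 3.30 ± 0.120 on X to 17.5 ± 1.39 on III (SD, n = 2 throughout).

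**Figure D1:**
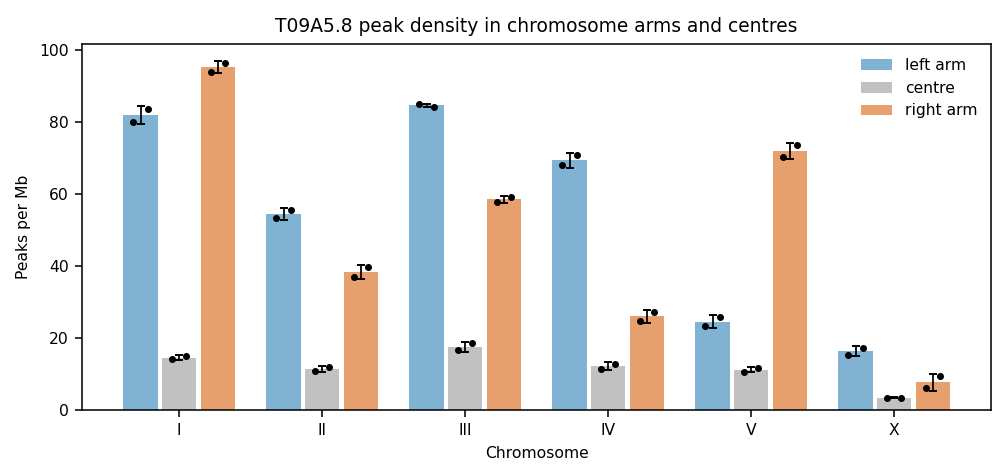
Peak density (peaks per Mb) in the left arm, centre and right arm, each 1 of 3 equal parts of a chromosome, for chromosomes I to V and X. Bars are means of 2 ChIP replicates, error bars are SD and points are the replicates. The centre is the lowest bar on every chromosome, and the right arm of V and the left arm of IV stand above the opposite arm.

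Peak coverage concentrated in a few stretches of the arms. As means of the replicates, the 10 most covered of 100 bins of 1 Mb held 36.9% of the covered bases. The bins leave out the end pieces beyond 15 Mb on I and II and beyond 17 Mb on IV. The last bins of III, V and X are shorter than 1 Mb. Coverage was over 30% in 15 bins, of which 6 lie on I, 3 on III, 3 on V, 2 on IV, 1 on II and 0 on X. The most covered bins in the replicate lists were from 14 to 15 Mb on I, with 52.6 ± 1.16% of bases, and from 1 to 2 Mb on III, with 51.99 ± 0.00665% (SD, n = 2). Chromosome V reached 47.7 ± 0.307% from 18 to 19 Mb, IV reached 44.6 ± 1.69% from 1 to 2 Mb and II reached 41.0 ± 3.03% from 1 to 2 Mb. Coverage was under 5% in 30 of 82 autosomal bins and in 16 of 18 bins of X. The order differed in the whole-series list, where the bin from 17 to 18 Mb on V was the most covered, at 79.0% against 36.5 ± 3.66% in the replicates (SD, n = 2). That list covered 59.1% of the bin from 1 to 2 Mb on III and 50.1% of that from 14 to 15 Mb on I. On X it covered 39.9% of the bin from 1 to 2 Mb, against 16.1 ± 3.84% in the replicates (SD, n = 2), so the count of 0 on X holds for the replicate lists alone.

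**Figure D2:**
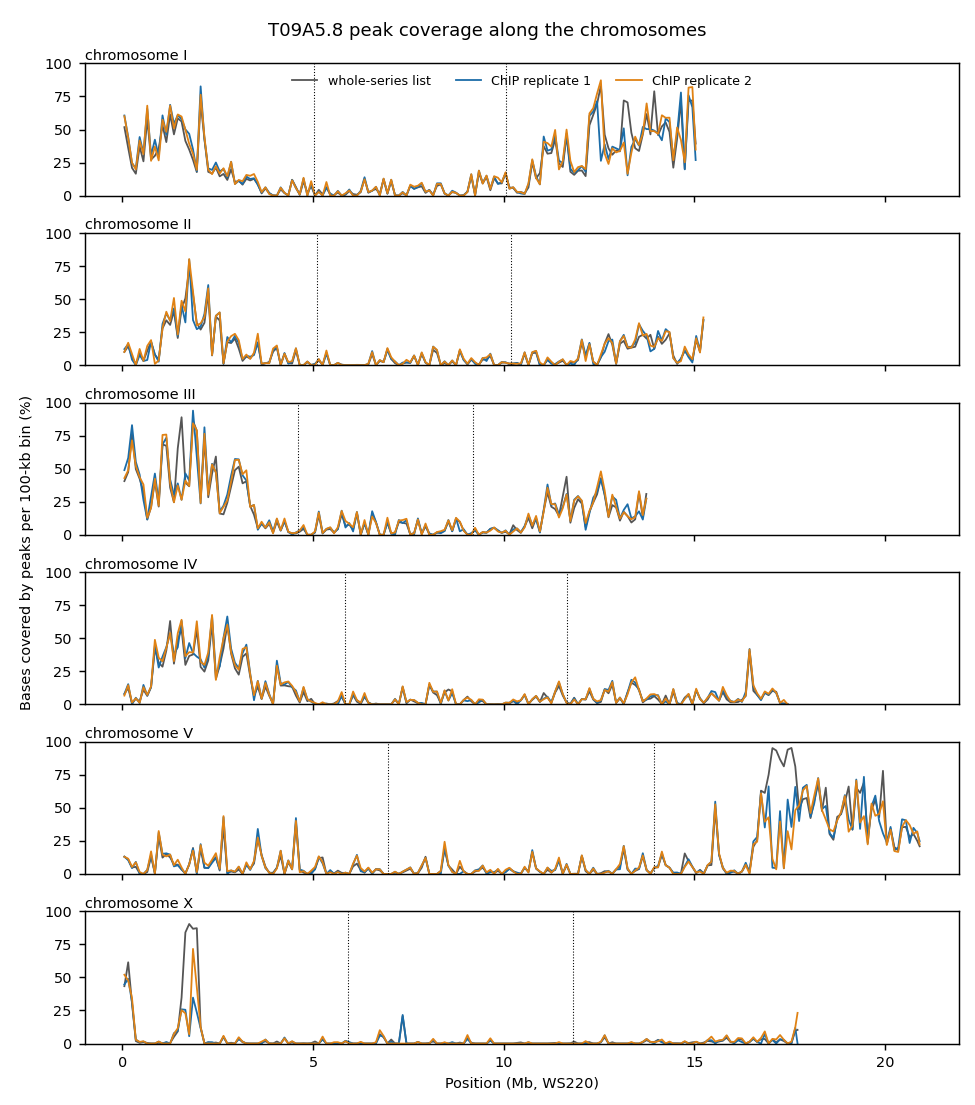
Percentage of bases covered by peaks in bins of 100 kb along each chromosome (position in Mb on WS220), for ChIP replicate 1, ChIP replicate 2 and the whole-series list. Dotted lines part arms from centres. Coverage is on average higher in arms than in centres, but it is not high at every chromosome end. In the last bin of IV, from 17400001 to 17493838, it is 0% in both replicates. The whole-series line rises above both replicates from 17000001 to 17600000 on V and from 1600001 to 2000000 on X.

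Of the 10 highest-scoring whole-series peaks found in both replicates, 9 lie on chromosome III, 6 of them on its left arm. Among the 25 highest, 13 lie on III, 4 on I, 4 on IV, 2 on II, 1 on V and 1 on X. The highest, with a score of 135.97, spans III 1910714 to 1933021. With a neighbour of score 125.21 at 1933051 to 1943821, it falls within a single peak of each replicate, from 1910488 to 1950944 in replicate 1 and from 1910415 to 1950354 in replicate 2. These are the widest peaks of the replicate lists, at 40457 and 39940 bp. The others on the left arm lie at 1083749 to 1094839 (131.96), 1819484 to 1827613 (126.13), 1860926 to 1865545 (118.76) and 1064966 to 1079902 (116). On the right arm of III are 13521088 to 13534867 (118.2) and 12609267 to 12617815 (116.93). One lies in the centre of III, at 7708813 to 7713744 (128.02). The remaining one is on the left arm of II, at 2920916 to 2924805 (124.36). All 10 carry the pile-up score of 3100 in both replicates, so the replicate scores do not rank them. Positions are WS220, and what is annotated there was not analysed here.

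In 13 of 1005 bins of 100 kb, the whole-series list covered at least 30 percentage points more than the mean of the replicates. This comparison was chosen after the data were seen. It averaged 87.1% of bases there, against 24.2% in replicate 1 and 27.05% in replicate 2. Of the bins, 7 lie on V, 4 on X, 1 on I and 1 on III. The whole-series peak with the highest score of all, 143.52 at III 1484568 to 1508928, overlaps no peak of either replicate. The nearest peaks of replicate 1 lie 119.25 kb apart around it, and those of replicate 2 lie 119.09 kb apart. Values for the right arm of V and the left arm of X therefore depend on the list. The whole-series list covered 35.6% of the right arm of V and 9.82% of the left arm of X, and the replicates covered 27.8 ± 1.00% and 5.73 ± 0.831% (SD, n = 2). Without these bins the X-to-autosome ratio was 0.185 in the replicates and 0.209 in the whole-series list, and the arm-to-centre log2 ratio was 2.08 and 2.26.

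**Figure D3:**
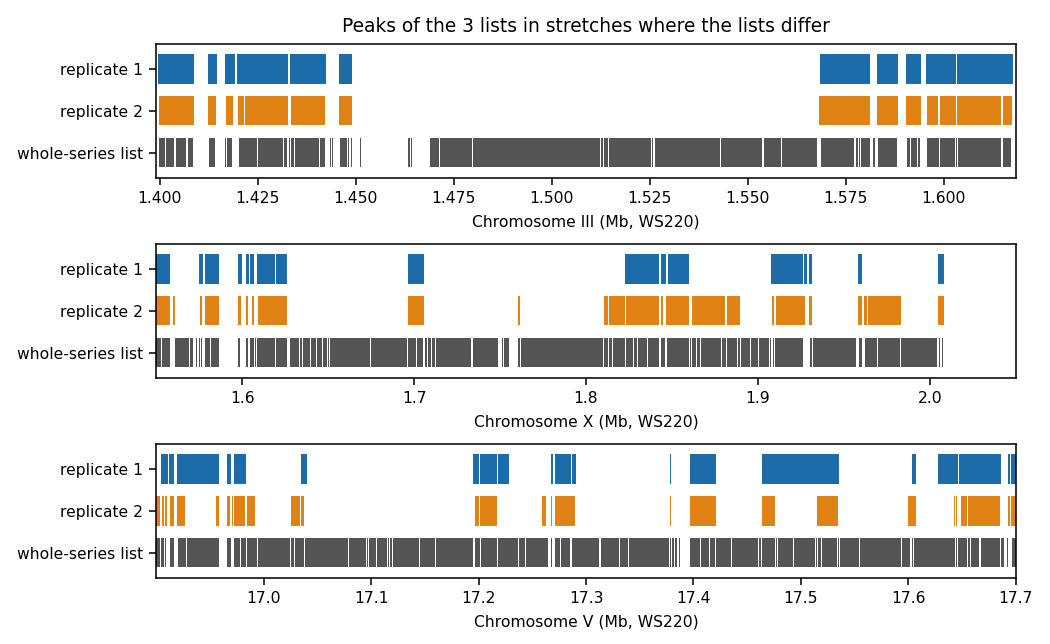
Peaks of replicate 1, replicate 2 and the whole-series list (boxes, to scale) in stretches of chromosomes III, X and V, with positions in Mb on WS220. The whole-series list is nearly continuous where both replicate lists have gaps, such as the gap of 119.25 kb in replicate 1 on III.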

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

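The overlap of replicates, the X-to-autosome ratio and the arm-to-centre ratio kept their direction under every alternative that was run for them. The p-values of the overlap and arm tests were at the smallest their shifts or sign flips allow under each alternative, and those of the X tests were far below the threshold, so the range of the values, not the p, shows how far a result moved. The overlap of replicates lay between 87.3 and 91.4% for replicate 1 and between 84.8 and 87.9% for replicate 2 over all settings, and every setting exceeded its shifts (100 shifts for the rule of 50% of the shorter peak, 1000 for the others). The shifts of 50 to 500 kb change only the chance level. The share of whole-series peaks found in both replicates, 53.8%, moved to 50.7% when at least 50% of the shorter peak had to be shared, to 63.0% when peaks were widened by 250 bp, and to 47.3% among the better-scoring peaks of each list, where the replicate lists are shortened as well; against the full replicate lists, 893 of the 1000 highest-scoring whole-series peaks were in both. The X-to-autosome ratio lay between 0.16, among the better-scoring peaks, and 0.264, in the whole-series list. In the replicate lists it moved from 0.207 to 0.183 when covered bases replaced peaks, and was 0.19 to 0.223 with either replicate left out. The ratio by covered bases was not computed for the whole-series list. The arm-to-centre log2 ratio lay between 2.08 and 2.47, and was 2.09 to 2.11 with either replicate left out. Spearman's rho of scores moved from 0.75 to 0.891 when only one-to-one overlaps were kept; the cause was not tested. No paired analysis was possible because the input samples that share replicate numbers with the ChIP samples have no peak list. The planned tests of gene features, repeats and gene lists were not run, since no annotation of WS220 was used here. The lists hold no read counts, so how far depth limits the number of peaks is unknown.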

Other observations

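The comparisons of opposite arms, of peak width and of spots on X in this part, and the score test of the missing stretches, were chosen only after the results were seen.

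The difference between the arms of a chromosome exceeded counting error on each of the 6 chromosomes in both replicates. The right arm was denser on V, by 2.94-fold, and on I, by 1.16-fold. The left arm was denser on IV by 2.67-fold, on X by 2.18-fold, on III by 1.45-fold and on II by 1.42-fold. These folds are means of the replicates. The left-over-right log2 ratio of X was 1.36 in replicate 1, 0.891 in replicate 2 and 1.72 in the whole-series list. That of V was -1.60, -1.51 and -1.83 in the same order. In the whole-series list the denser arm was the same on each chromosome. Over the 12 two-sided exact binomial tests, the adjusted p ran from 3.9e-38 for V in replicate 1 to 0.036 for I in replicate 2, and these tests take peaks as independent, which neighbouring peaks are not. Peak width showed no common direction between arms and centres. The median width in arms over that in centres had a mean log2 ratio of -0.0058 over the 6 chromosomes (two-sided exact sign-flip test, p = 0.97), and was above 0 on V, at 0.13 ± 0.05, and X, at 0.46 ± 0.10 (SD, n = 2), and below 0 on the other 4. The centre of X held only 19 peaks in replicate 1 and 20 in replicate 2. Peaks of 10 kb or more made up a larger share in arms than in centres, 5.51% against 3.32% in replicate 1, 5.10% against 2.77% in replicate 2 and 0.569% against 0.24% in the whole-series list, differences that were not tested. In centres these shares rest on 12 peaks in replicate 1, 11 in replicate 2 and 3 in the whole-series list.

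On X, binding gathered in a pair of spots on the left arm, from the left end to 0.4 Mb and from 1.5 to 2.1 Mb. They make up 5.64% of the length of X and held 60.4 ± 0.667% of its covered bases and 43.8 ± 2.85% of its peaks (SD, n = 2). The first held 28.1 ± 2.78% of the covered bases and the second 32.3 ± 3.44%. In the whole-series list the shares were 19.2% and 55.5%. The rest of X had 5.41 ± 1.06 peaks per Mb, which covered 1.12 ± 0.146% of it. No test was made of the spots, since their limits were set from the same peaks.

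In 13 bins on V, X, III and I, the whole-series list covered 70.5 to 95.3% of bases and the mean of the replicates was at least 30 percentage points lower, although single replicates reached 71.6% on X and 56.3% on V. The 228 whole-series peaks there without a replicate peak had a median score of 19.9 against 10.2 for peaks in both replicates. Bins picked for coverage hold wide peaks, however. Against shared peaks of like width, the median log2 ratio of scores was 0.012 (95% interval from resampling the 13 bins, -0.31 to 0.23). Their median score was thus no lower than that of like-width shared peaks, so a low whole-series score did not set them apart. That score is on another scale than the replicates' scores. It cannot show whether enrichment in each replicate was too weak for the replicate lists. Weak enrichment in the replicates stays open, and the interval of the whole-series scores itself reaches -0.31. Another candidate explanation is that the replicate lists lost very wide continuous domains in calling or filtering. With whole-series peaks joined over gaps of up to 500 bp, the 14 domains over 40 kb had a median of 1.78% of their bases covered in replicate 1 and 7.17% in replicate 2, against 93.9% and 93.5% for the 50 domains of 20 to 40 kb, but 12 of the 14 lie in the bins that drew attention. The 2 outside had a median of 74.4% in replicate 1 and 45.7% in replicate 2, and went apart. The one on V, next to those bins, was 49.5% and 11.5% covered. The one on III, from 1857402 to 1908333, was 99.4% and 79.9% covered. A peak there ended at 1880750 in replicate 1 and at 1880689 in replicate 2, short of the domain's end. The coverage of this domain thus cannot show whether a replicate peak as wide as the domain would have been kept. The widest replicate peaks, 40457 and 39940 bp, leave a loss of wider ones open. Outside the bins, the domains under 10% covered in both replicates were 2264 of 5614 under 5 kb, 9 of 425 of 5 to 10 kb, 3 of 191 of 10 to 20 kb, 6 of 40 of 20 to 40 kb and 0 of 2 over 40 kb, so neither explanation is settled, differences in the control or the caller stay open too, and no biological explanation was tested, because the lists describe the same samples.

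In replicate 2, a larger share of the peaks on X than of those on autosomes was unshared, 31.6% against 13.8%. If the unshared peaks on X were merely weak, the excess should vanish among peaks of like score. With peaks ranked by score into 5 groups of equal number, the Mantel-Haenszel odds ratio of being unshared, X against autosomes, was 2.55, with a lower 95% limit of 1.76. The limit covers counting error only, since neighbouring peaks are not independent. As far as counting error goes, the value argues against low score as the whole cause. In replicate 1 the odds ratio was 0.809 (0.462 to 1.42). A difference between the libraries stays open and was not tested, and X was singled out after the values were seen.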
